A study of Homo sapiens with 24 samples.

How the data were processed

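RNA was measured on 24 two-colour human gene expression microarrays of a single Agilent design. Each array compared everolimus-treated cells, labelled with Cy5, with untreated cells of the same line and biological replicate, labelled with Cy3, and no array had the dyes exchanged. The 2 lines, parental clear cell renal carcinoma cells and renal cancer stem cells (CSC), each had 3 biological replicates, and each replicate was hybridized to 4 technical arrays. The 3 slides each held 1 replicate of both lines, and the lines lay in different slide positions, so slide position and line cannot be told apart.

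Per the file headers, the scans were quantified with Agilent Feature Extraction, whose spot tables give signal and background as intensity and the treated-over-untreated ratio as log10, after Agilent's dye normalization and background steps. The deposited table of normalized values is in log10 and equals the log10 ratio of the spot tables exactly, with a largest difference of 0, and each of its columns had a median of 0. The spot tables give median signals and no mean signals, so median signals were used where mean signals had been planned. The spot tables also give no gene symbols, so the RefSeq accession of each probe was matched to a symbol in a RefSeq gene table, which gave a symbol to 31104 of 58201 probes and 22439 distinct symbols. No probe coordinates are given, because the array design and the gene table rest on different genome builds.

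Each array held 62976 spots, of which 2075 were controls. Control spots were left out and spots that Feature Extraction marked as non-uniform or as outliers were set to missing. Signals were background-corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3 with the data.table package (version 1.17.8). A probe was kept where its signal was well above background on at least 9 of the 12 arrays of at least 1 of the 4 combinations of line and treatment, which left 24286 probes. The brightest kept probe stood for each gene, which left 20638 genes, 13543 of them with a symbol. The 4 technical arrays of a replicate were averaged, so the test unit was the biological replicate.

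limma's moderated test was fitted to the 6 replicate log2 ratios for the response of each line and for the difference between the responses. The Cy3 and Cy5 channels were compared between lines separately, after quantile normalization of average intensity across arrays. P-values were adjusted by Benjamini-Hochberg over the 20638 genes and called at 0.05. A fit on the 3 CSC replicates alone had been planned as an alternative. Its use for the named genes and gene lists of the CSC response, and the alternatives to its processing, were chosen after the shared fit had made 0 calls. P-values measure the spread between these samples, since the labels do not say whether the replicates were separate cultures, and the number of arrays limits the precision.

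Before the data were examined, 27 gene lists were fixed with 574 distinct genes, of which 561 were on the array. The comparisons, the main processing, most alternatives and the rule for named genes were fixed at the same time. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative, and with fry. For each comparison the rule named the 12 largest rises and the 12 largest falls among called genes that had a symbol and moved the same way in all 3 replicates, or whose replicates did not overlap between lines. Genes on the Y chromosome, the transcripts of X inactivation and genes of alternative haplotypes were left out of the naming. The rule also named the members of each list with the smallest p-values and a fixed set of genes of the mTOR pathway, growth, stemness and renal lineage. CA9, PROM1 and CDH1 belonged to that set and were not measured above the filter.

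Alternatives covered background correction, normalization, the deposited log10 ratios, the filter on dim probes (a strict form kept 12096 probes), the choice of probe and the variance model. They also covered unpaired channels, the replicate number and slide as a block, and each replicate left out. A further alternative, called the arrays as units below, took the single technical arrays with the biological replicate as a random block. The pipeline was tested on simulated data built from these arrays, with 200 of 20638 genes changed. With CSC replicates alone it recovered 44 of 67 genes changed by 0.5 on the log2 scale, 63 of 67 changed by 1 and 65 of 66 changed by 2, with 5 false calls. With the spread shared by both lines, in a separate simulated draw, it recovered 13, 27 and 41 of as many genes of these sizes. That draw gave 0 false calls in the CSC line. In the parental line it recovered 20, 36 and 51 with 456 false calls, and 1 of the smallest changes was called with the wrong sign. False calls numbered 94 for the difference between responses, 30 for the untreated comparison and 51 for the treated comparison. A simulated list shifted by 1 on the log2 scale was called in each comparison, and 0 of 20 unshifted lists were. Simulated genes varied independently of each other, so this does not test list calls where the genes of a list move together. An early form of this test that allowed 0 wrong signs failed and was relaxed to a limit on the mean error of the estimates.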

Results

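Everolimus, a drug that binds FKBP1A and blocks the mTOR kinase complex that drives protein synthesis and growth, is given to patients with renal cancer. The series measured RNA from 2 commercial cell lines of clear cell renal carcinoma after 3 days of everolimus. The parental line received 4 µM and the cancer stem cell (CSC) line 5 µM, so dose and line differ together. Each line had 3 biological replicates with 4 technical arrays each, and each array paired treated with untreated RNA of the same replicate. Between 24.6% and 30.6% of probes lay well above background in untreated parental RNA on single arrays, and between 35.4% and 48.7% in treated parental RNA. The ranges were 23.9% to 26.9% in untreated and 29.8% to 32.3% in treated CSC RNA.

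The treated parental RNA of replicates 1 and 3 stood apart from the other RNAs. These correlated with each other across genes at r = 0.998, with treated parental replicate 2 at 0.768 and 0.765, and with CSC RNAs at 0.430 to 0.448. Their correlations with the untreated RNA of the same replicate were 0.585 and 0.599. In contrast, untreated and treated CSC RNA of the same replicate correlated at 0.986, 0.991 and 0.993. Untreated parental replicate 2 correlated with untreated CSC RNAs at 0.990 to 0.992, above its 0.979 and 0.973 with the other untreated parental replicates. Treated parental replicate 2 correlated at 0.926 and 0.933 with the untreated RNA of parental replicates 1 and 3, above its 0.893 with untreated RNA of its own replicate. These correlations are across genes, which are not independent replicates.

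**Figure D1:**
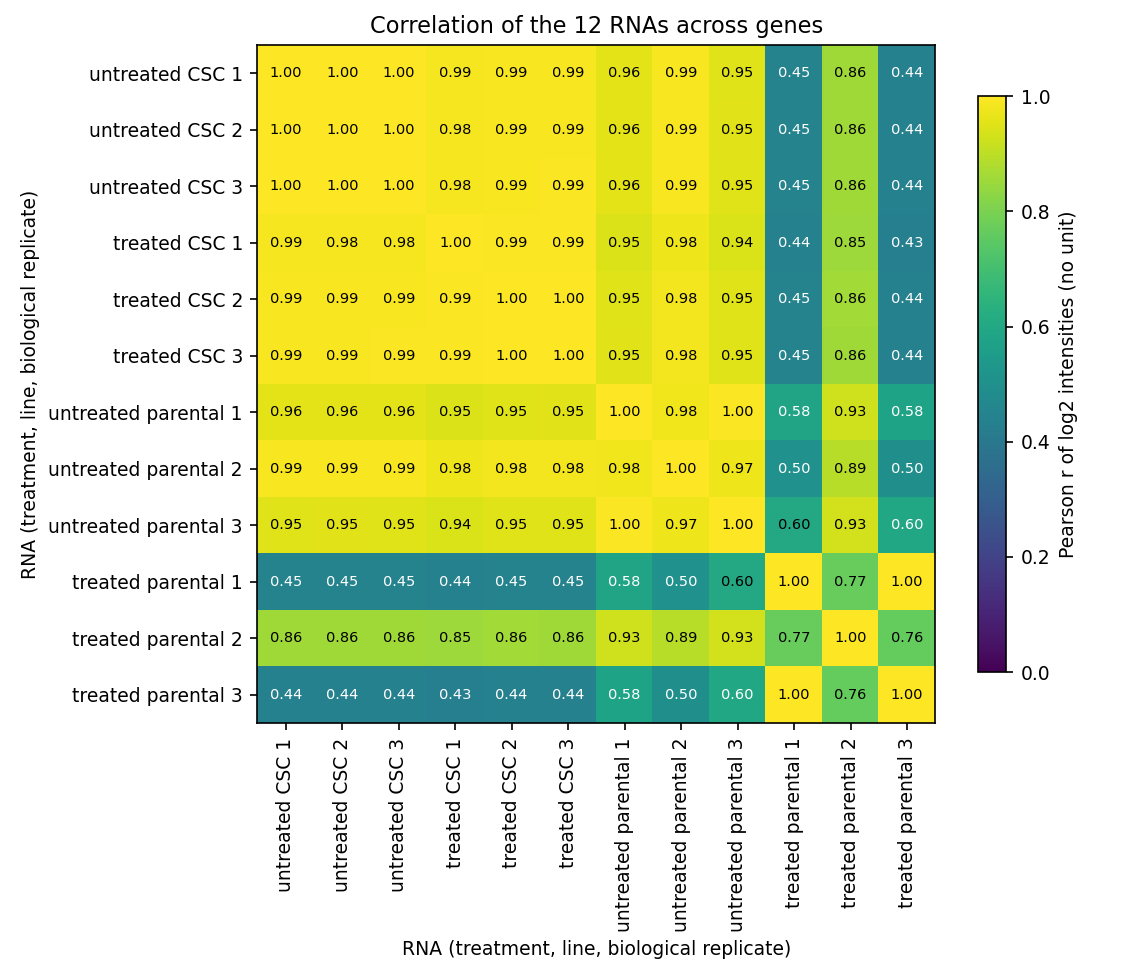
Pearson correlation across genes of the log2 intensities of the 12 RNAs, each the mean of 4 technical arrays. The treated parental RNA of replicates 1 and 3 correlated at 0.998 with each other and at 0.430 to 0.605 with RNAs of the other conditions.

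The response of the CSC line asks what everolimus changes in cells with stem-like properties. In the treated cells, GADD45A, DDIT3 and CHAC1, genes of stress and growth arrest, were among the largest rises, although no list of such genes passed camera. By camera with a preset correlation, the lists of glycolysis genes, targets of the hypoxia-inducible factor (HIF) and ribosomal protein genes were higher and that of mitosis genes lower. Their genes called that way were 7 of 18, 8 of 16, 24 of 35 and 8 of 24, and the 4 list calls were lost with an estimated correlation and with fry. The genes that encode the mTOR complexes moved little or were too dim to measure.

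GADD45A, which halts the cell cycle after DNA damage, rose by 2.44 on the log2 scale (SE 0.18, n = 3, limma adjusted p = 0.00199). DDIT3, a transcription factor of the stress response, rose by 2.23 (SE 0.18), and CHAC1, which degrades glutathione under the same response, rose by 1.73 (SE 0.18). CLCN5, an endosomal chloride transporter of the renal tubule, rose by 2.18 (SE 0.04, adjusted p = 0.000433). The tetraspanin CD9, the matrix proteoglycan DCN and the glucose transporter SLC2A1 rose by 2.07, 1.82 and 1.78. NOL4, a nucleolar protein, was at least 4.39-fold higher, because its untreated RNA was well above background on 0 of 12 arrays. ID2, an inhibitor of differentiation factors, fell most among called genes with a symbol, by 2.19 on the log2 scale (SE 0.13, adjusted p = 0.0015). The growth factor NRG2 fell by 2.08 on the log2 scale and CRIP1, a LIM-domain protein, fell by 2.01. The nuclear importer KPNA2 (-1.93), the cyclin CCNA2 (-1.87) and the tubulins TUBA4A (-1.86) and TUBA1C (-1.78) fell too. HSPA8, the constitutive heat shock chaperone, fell by 1.76 on the log2 scale. Each of these genes moved the same way in 3 of 3 replicates, which the naming rule required.

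**Figure D2:**
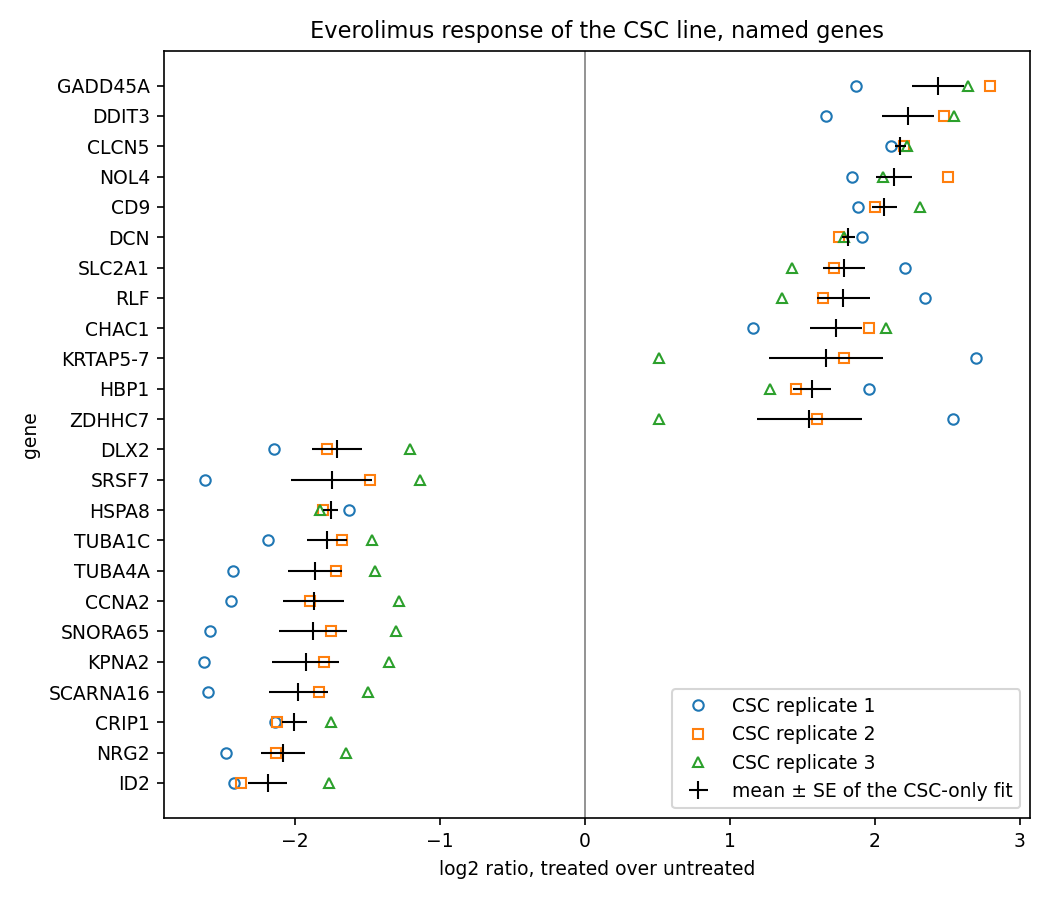
Log2 ratios of treated over untreated CSC RNA for the 12 largest rises and 12 largest falls, with a symbol per biological replicate and the mean and SE of the fit on the CSC replicates. All 3 replicates lie on the same side of 0 for each gene, which the naming rule required, from GADD45A at 2.44 to ID2 at -2.19. The point of NOL4 is a fitted value whose untreated RNA was not well above background.

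Among the genes followed for mTOR and growth, VEGFA, which drives vessel growth, rose by 1.06 in the CSC line and DDIT4, an upstream inhibitor of mTOR, by 0.87. RICTOR, a subunit of the second mTOR complex, rose by 0.43 and the translational repressor EIF4EBP1 by 0.35. The cyclin CCND1 (-1.08), the proliferation marker MKI67 (-0.88) and the filament gene VIM (-0.71) fell. The drug's binding partner FKBP1A fell by 0.40 on the log2 scale and the adhesion receptor CD44 fell by 0.34, but with median centring in place of loess both were higher, by 0.16 and 0.12, and 1 of 4 other FKBP1A probes moved the opposite way. RPS6KB1, MYC, ENG, ALDH1A1, PAX8 and CDKN1A were not called, with RPS6KB1 at -0.30 (adjusted p = 0.0878). MTOR and RPTOR were well above background on 0 of 12 arrays in either group, so no ratio is given.

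Of 35 measured ribosomal protein genes, 24 rose and 0 fell, and 25 rose when adjusted over the list alone (camera adjusted p = 4.34e-07; p = 0.151 with an estimated correlation). RPL38 rose by 0.85 and RPLP1 by 0.60. Of 24 mitosis genes, 8 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00698; p = 0.135 with an estimated correlation), with CDK1 at -0.77 and CCNB1 at -0.94. Of 16 HIF targets, 8 rose and 2 fell, and 10 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0132; p = 0.19 with an estimated correlation). The histone demethylase KDM3A rose by 1.35 and BNIP3L, which clears mitochondria, by 1.16. Of 18 glycolysis genes, 7 rose and 0 fell, and 8 rose when adjusted over the list alone (camera adjusted p = 0.0342; p = 0.318 with an estimated correlation). PFKL, PGAM1 and ENO1 rose by 1.20, 1.08 and 1.02. The direction of these 4 lists was the same under each scaling tried, but with an estimated correlation camera called 0 of 27 lists after adjustment (the p-values given for it are unadjusted), and fry called 0.

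The autophagy and lysosome list did not pass camera: 6 of 24 genes rose and 0 fell, 8 when adjusted over the list alone (camera adjusted p = 0.382), with the membrane protein LAMP1 at 0.93 and the protease CTSA at 0.85. Of 26 ATF4 targets, 7 rose and 1 fell, and 7 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.643). Their median flipped from 0.02 to -0.06 with Agilent's processed signals. Of 27 mTOR pathway components, 6 rose and 4 fell, and 7 and 6 when adjusted over the list alone (camera adjusted p = 0.894), with the cap-binding factor EIF4E at -0.66 and its repressor EIF4EBP2 at -0.72. Their median was 0.00 and became -0.03 with processed signals and 0.28 with median centring, and camera's direction was down although the mean was 0.00. Of 13 stem cell markers, 0 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.427). Their median of -0.03 became 0.09 with median centring.

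In total, limma called 4083 of 20638 genes in the CSC replicates alone, with 2255 higher and 1828 lower, and 189 of them also changed by at least 1 on the log2 scale. With median centring the count was 10847, with 10069 higher and 778 lower, and the median of all genes was 0.15 in place of 0.01. The shared fit of both lines called 0 genes, with 765 at an unadjusted p under 0.05 and a lowest adjusted p of 0.26, against 2960 genes with unpaired channels, 698 with median centring, 393 with scale normalization and 312 with the arrays as units. Without CSC replicate 2 the CSC fit called 0 genes, with 4105 at an unadjusted p under 0.05, and without CSC replicate 3 it called 2658.

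The response of the parental line asks the same question for cells that were not described as stem-like. By camera with a preset correlation, its treated RNA was higher in lists of growth and energy supply: ribosomal proteins, respiratory chain, glycolysis and sterol synthesis. So were targets of HIF, ATF4, which answers amino acid shortage, and NF-kB, which drives inflammation, but each of these list calls was lost when camera estimated the correlation. The treated RNA of replicates 1 and 3 correlated with untreated RNA of the same replicate at only 0.585 and 0.599. Whether these lists reflect a response to the drug or another source of that RNA stays open. The gap junction gene GJA1 and the renal calcium channel TRPV5 were among the largest falls, while the lists of renal and epithelial genes did not pass camera.

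Among called genes with a symbol, SLC66A1, which exports cationic amino acids from lysosomes, rose most, by 7.96 on the log2 scale (SE 0.30, n = 3, limma adjusted p = 5.2e-05). The ribosomal protein RPL19 rose by 7.13, the arsenic methyltransferase AS3MT by 6.86, the histone H4C3 by 6.70 and the metal-binding protein MT2A by 6.63. ATP5F1E, a subunit of the mitochondrial ATP synthase, rose by 7.28, with untreated RNA well above background on 8 of 12 arrays. ATF4 rose by 6.90 and the host of small nucleolar RNAs SNHG5 by 6.92, each with untreated RNA well above background on 9 of 12 arrays. GJA1, the gap junction protein connexin 43, fell most of these genes, by 5.24 on the log2 scale (SE 1.38, adjusted p = 0.026), with treated RNA above background on 10 of 12 arrays. Its ratios were -7.35, -0.78 and -7.57 in replicates 1, 2 and 3. The integrin ITGB4 fell by 5.07 on the log2 scale (replicates -6.57, -1.84 and -6.79) and the renal calcium channel TRPV5 fell by 5.02 (replicates -7.24, -0.33 and -7.49). SELENOP, a selenium carrier, fell by 5.19 on the log2 scale, with treated RNA above background on 4 of 12 arrays. The detoxifying enzyme GSTM2 (-4.95), the Wnt factor TCF7L1 (-4.63) and the nephron progenitor gene CITED1 (-4.57) followed. The rises were large in each of the 3 replicates, while the falls rested on replicates 1 and 3. The SE and adjusted p come from the fit that shares its spread with the CSC line. With the parental replicates alone, 10 genes in all were called lower, and 22 named genes of this response lost their call.

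Among the genes followed for mTOR and growth in the parental line, the mTOR inhibitor DDIT4 rose by 2.91 (SE 0.15), EIF4EBP1 by 2.75 (SE 0.29) and RPTOR, the scaffold of the first mTOR complex, by 2.32 (SE 0.21), the last with untreated RNA above background on 8 of 12 arrays. MTOR was at least 1.57-fold higher, since its untreated RNA was above background on 0 of 12 arrays, and RICTOR rose by 0.50. FKBP1A had a ratio of -3.11, but 3 of its 4 other probes moved the opposite way. The S6 kinase RPS6KB1 had a ratio of -2.76, with 1 of 2 other probes opposite, and CD44 one of 3.42 with its 1 other probe opposite. VIM rose by 2.97, PAX8, a renal lineage factor, by 1.74, VEGFA by 1.38 and MYC by 0.68. CCND1 had a ratio of -0.61, which became 0.70 with median centring. MKI67 had a ratio of -0.92 with both other probes opposite, 0.68 with median centring and 0.47 with the mean of its probes, and ALDH1A1 went from -1.13 to 0.14 with the mean of its probes. CDKN1A and ENG were not called, at adjusted p = 0.0694 and 0.0611.

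In the parental line 13 of 27 lists passed camera, all with more genes higher than lower, and none of the 13 changed the sign of its median under a scaling. With an estimated correlation camera called 0 of the 27 after adjustment, and the p-values given for it are unadjusted. Of 18 glycolysis genes 16 rose and 0 fell, 17 when adjusted over the list alone (camera adjusted p = 5.46e-07; p = 0.0142 with an estimated correlation), with PKM at 3.94 and TPI1 at 3.73. Of 21 sterol genes 17 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 7.21e-06; p = 0.0358 with an estimated correlation), with the isoprenoid enzyme FDPS at 2.92. Of 35 ribosomal protein genes 25 rose and 3 fell, 27 and 4 when adjusted over the list alone (camera adjusted p = 9.46e-06; p = 0.171 with an estimated correlation), with RPL32 at 5.69. Of 27 oxidative phosphorylation genes 18 rose and 5 fell, 18 and 6 when adjusted over the list alone (camera adjusted p = 0.000322; p = 0.0414 with an estimated correlation), with NDUFV1 at 2.71. Of 16 HIF targets 11 rose and 2 fell (camera adjusted p = 0.00163; p = 0.0212 with an estimated correlation), with NDRG1 at 4.19. Of 26 DNA replication genes 19 rose and 2 fell (camera adjusted p = 1.14e-05; p = 0.042 with an estimated correlation), with thymidine kinase TK1 at 5.55. For both of these lists the counts were the same when adjusted over the list alone.

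Of 26 ATF4 targets in the parental line 20 rose and 1 fell, 20 and 2 when adjusted over the list alone (camera adjusted p = 7.21e-06; p = 0.0701 with an estimated correlation). NF-kB targets rose in 14 of 15 cases and fell in 1 (camera adjusted p = 8.39e-05; p = 0.226 with an estimated correlation). Autophagy and lysosome genes rose in 16 of 24 and fell in 2 (camera adjusted p = 0.000592; p = 0.017 with an estimated correlation), with the receptor SQSTM1 at 3.60. Ribosome biogenesis genes rose in 17 of 24 and fell in 4 (camera adjusted p = 0.000431; p = 0.0692 with an estimated correlation), with the methyltransferase FBL at 4.54. NRF2 targets rose in 10 of 15 and fell in 1 (camera adjusted p = 0.0103; p = 0.161 with an estimated correlation), with the ferritin FTL at 4.78. Fatty acid genes rose in 9 of 13 and fell in 2 (camera adjusted p = 0.0103; p = 0.182 with an estimated correlation). Mitosis genes rose in 15 of 24 and fell in 8 (camera adjusted p = 0.0143; p = 0.101 with an estimated correlation). These last 6 counts were the same when adjusted over the list alone. The p-values with an estimated correlation are unadjusted here too, and after adjustment none of these lists was called with it. Of 27 mTOR components 11 rose and 16 fell, also when adjusted over the list alone, with a median of -0.90 and a mean of -0.37. camera's direction was up for this list (adjusted p = 0.724), and its median became 0.21 with median centring.

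**Figure D3:**
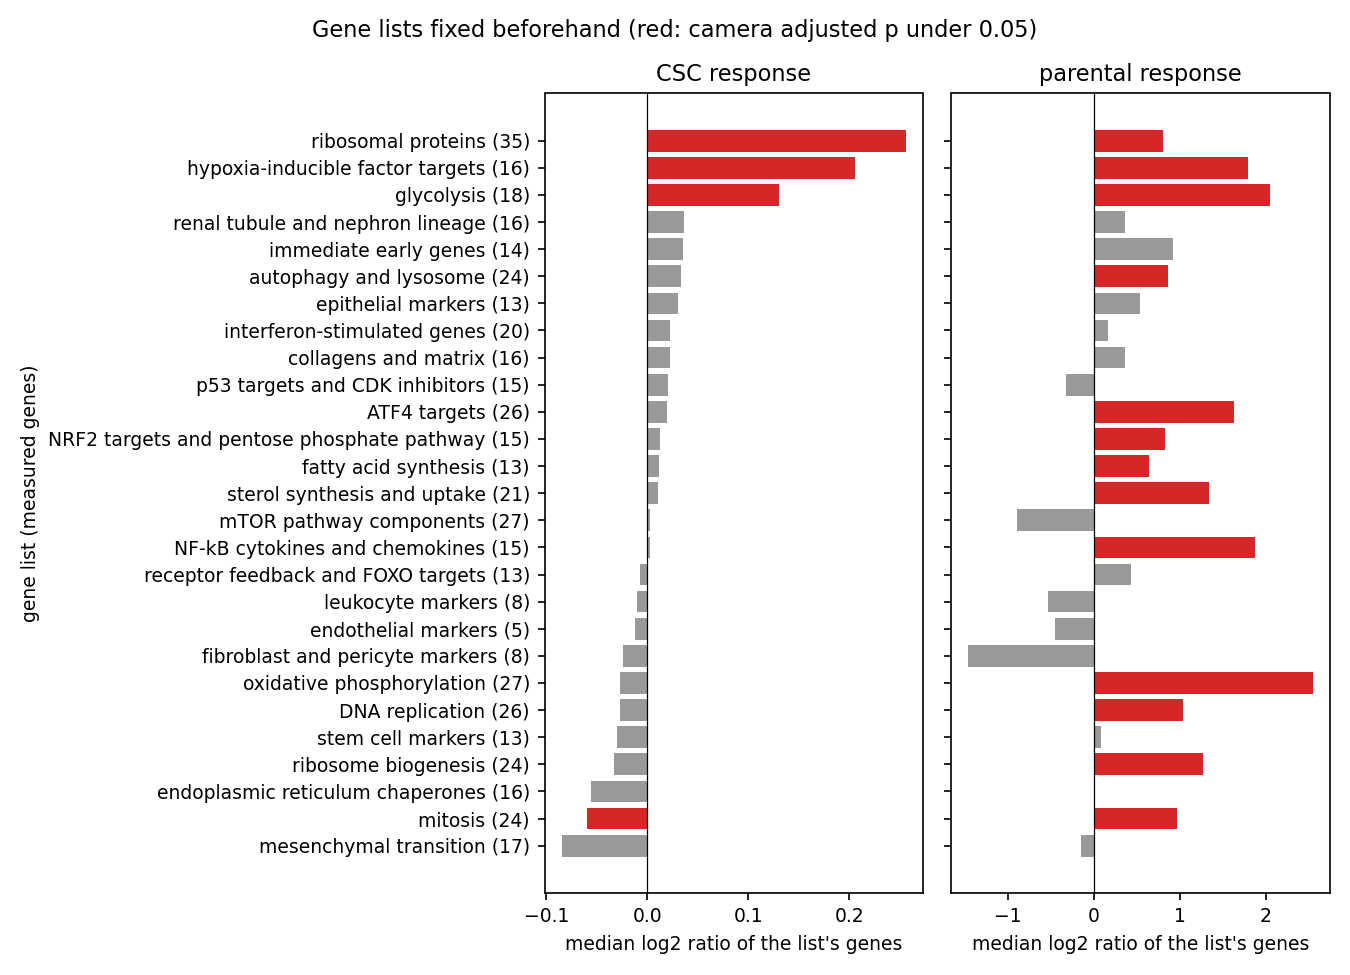
Median log2 ratio, treated over untreated, of the fitted values of each gene list in the CSC line and in the parental line, on 2 different scales, with the number of measured genes and with lists at a camera adjusted p under 0.05 in red. The red lists kept their direction under each scaling; with median centring or processed signals, grey lists that changed sign included mTOR components in both lines and, in the parental line, mesenchymal transition and p53 targets.

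In total, limma called 16024 of 20638 genes in the parental line, 6539 higher and 9485 lower, and 8434 of them also changed by at least 1 on the log2 scale. With median centring the split was 9682 higher and 2182 lower. The median of all genes was -0.28 with loess, 0.29 with median centring and -0.62 with processed signals. The fit shares its spread with the CSC line and made 456 false calls on simulated data, and the parental replicates alone gave 2854 calls, 2844 higher and 10 lower. The count was 4974 without parental replicate 1 (4760 higher), 4659 without parental replicate 3 (4520 higher) and 19075 without parental replicate 2 (6877 higher). The SD of the log2 ratios over genes was 1.96, 0.886 and 1.91 in replicates 1, 2 and 3.

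Parental replicate 2 moved with replicates 1 and 3 where genes rose and hardly moved where they fell. Genes with a mean ratio of -6.40 in replicates 1 and 3 had a median of -0.24 in replicate 2, while genes with a mean of 6.43 had a median of 4.86. Across genes the ratios of replicate 2 correlated with those of replicates 1 and 3 at 0.770 and 0.762.

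**Figure D4:**
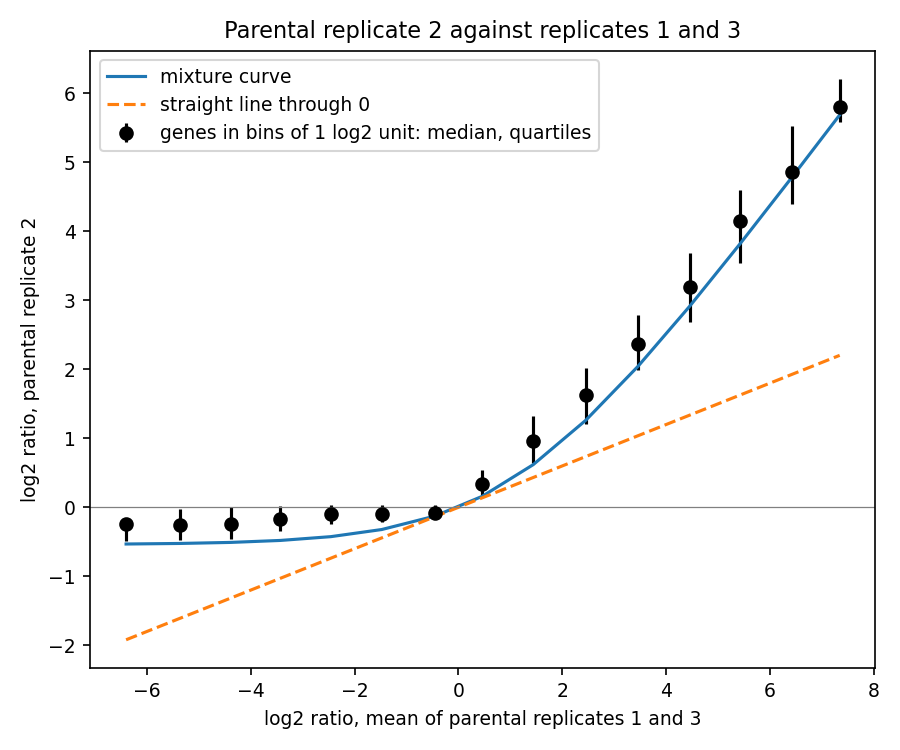
Median and quartiles of the log2 ratio of parental replicate 2 against the mean ratio of parental replicates 1 and 3, for genes in bins of 1 log2 unit, with the curve of a mixture of untreated RNA and 31.2% RNA like that of replicates 1 and 3, and a straight line through 0. Replicate 2 stays near 0 on the left, at -0.24 for genes at -6.40, and lies near the curve on the right, at 4.86 for genes at 6.43; the curve is below the quartiles in the bins from -6.40 to -1.48 and at 0.46 and 1.44.

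The difference between the responses asks whether the stem-like line answers the drug differently from the parental line. By camera with a preset correlation, lists of glycolysis, respiratory chain and sterol genes were lower in the CSC response than in the parental response, calls that were lost when camera estimated the correlation. These lists were also among those called higher in the parental response itself. The share of differing genes that were lower in CSC cells changed with the processing. The 2 lines shared no RNA, so the comparison is free of a common control.

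The largest differences among called genes with a symbol, CSC minus parental, were SLC66A1 at -7.64 (SE 0.42), ATP5F1E at -7.46, AS3MT at -7.31 and RPL19 at -7.05. TSR1, a ribosome assembly factor, was at -6.84 and MT2A at -6.79. On the other side, the T cell modulator BTNL8 was at 5.79 (SE 1.35), SERPINF1, an inhibitor of vessel growth, at 4.13, and the homeobox genes IRX5 and IRX3 at 3.60 and 2.45. The chromatin regulators JMJD1C and JARID2 were at 2.67 and 2.63 and the splicing kinase CLK1 at 2.46. Of the mTOR genes, EIF4EBP1 (-2.41), RPTOR (-2.37) and DDIT4 (-2.04) differed, as did CD44 (-3.77, its 1 other probe opposite), VIM (-3.69) and PAX8 (-1.69). VEGFA, CCND1, MYC, MKI67, RICTOR and FKBP1A were not called.

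By camera 13 of 27 lists were lower in the CSC response than in the parental response, but 0 after adjustment with an estimated correlation, whose p-values are given unadjusted. They were the same 13 lists that were called higher in the parental response. The SD of the log2 ratios over genes was 0.315, 0.254 and 0.218 in CSC replicates 1, 2 and 3. It was 1.96, 0.886 and 1.91 in the parental replicates, so the list differences largely repeat the parental response. DNA replication differed in 0 genes up and 16 down of 26, 18 down when adjusted over the list alone (camera adjusted p = 5.57e-06; p = 0.0345 with an estimated correlation). Sterol synthesis gave 0 and 14 of 21, 16 when adjusted over the list alone (camera adjusted p = 5.57e-06; p = 0.032 with an estimated correlation). Glycolysis gave 0 and 12 of 18, 15 when adjusted over the list alone (camera adjusted p = 1.1e-05; p = 0.0229 with an estimated correlation). Oxidative phosphorylation gave 0 and 18 of 27, 1 and 18 when adjusted over the list alone (camera adjusted p = 9.19e-05; p = 0.0317 with an estimated correlation). Mitosis gave 0 and 15 of 24, the same when adjusted over the list alone (camera adjusted p = 0.000675; p = 0.0429 with an estimated correlation). HIF targets gave 0 and 8 of 16, 1 and 10 when adjusted over the list alone (camera adjusted p = 0.00333; p = 0.0264 with an estimated correlation). NF-kB, ATF4 and NRF2 targets, ribosome biogenesis, autophagy and fatty acid genes were lower at camera adjusted p from 9.19e-05 to 0.00813, a call lost for each with an estimated correlation. Ribosomal proteins gave 1 and 10 of 35, 3 and 11 when adjusted over the list alone (camera adjusted p = 0.00216; p = 0.312 with an estimated correlation), and their median flipped from -0.41 to 0.12 with median centring and 0.01 with scale normalization.

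In total, 5207 of 20638 genes differed in their response by limma, 359 higher and 4848 lower in the CSC line, and 3133 of them by at least 1 on the log2 scale. The split was 7384 and 6533 with processed signals, 7382 and 6528 with the deposited log10 ratios, 1450 and 2915 with median centring, 1949 and 4667 with scale normalization and 7421 and 4667 with the arrays as units. The median of all genes was 0.30 in the main fit, 0.68 with processed signals and -0.03 with median centring. Without a single CSC replicate the count lay between 2747 and 2824; without parental replicate 1, 2 or 3 it was 3416, 18633 (12044 higher and 6589 lower) and 3138. With the slide as a block it was 2668; no test was possible inside a single slide, which held 1 replicate of each line.

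Across genes the mean responses of the lines correlated at r = 0.0524 (Spearman's rho 0.0155), and at -0.0328 with processed signals and -0.306 with median centring. With the parental calls of the shared fit and the calls of the CSC replicates alone, 410 genes were higher in both lines, against 714 expected from the separate counts. The count lower in both was 1395, against 840 expected, and 1168 genes moved in opposite directions, for which no expected count was computed. The expected counts take each gene as equally open to a call in either line. But 21396 probes passed the background rule in treated parental RNA, against 13605 and 16625 in untreated and treated CSC RNA. Genes too dim in CSC RNA to be called could by themselves move the counts away from those expected, which was not tested. Each array had Cy5 on treated RNA, so a dye effect specific to each gene could add to the genes moving together. The count lower in both rests on the shared fit, as the parental replicates alone gave 10 lower calls.

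The comparison of untreated cells asks how the stem-like line differs from the parental line before the drug. Untreated CSC cells had less RNA of the chaperone HSPB1, the ribosomal protein RPS26 and HLA-E, while the ribosomal protein list as a whole did not pass camera. They had more RNA of the axon guidance receptor PLXNA4 and the adhesion molecule NCAM1. For HSPB1, RPS26 and HLA-E the level of parental replicate 2 lay between the CSC level and the levels of parental replicates 1 and 3.

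Of the called genes with a symbol, HSPB1, a small heat shock chaperone, was lowest relative to parental cells, at -5.50 (SE 0.77, limma adjusted p = 0.0367), with CSC RNA above background on 10 of 12 arrays. Its log2 intensities were 12.63, 9.84 and 13.18 in the parental replicates against a CSC mean of 6.39. The ribosomal protein RPS26 was lower (-4.74), as were the non-classical antigen-presenting gene HLA-E (-3.72), the vesicle transporter SVOP (-3.71) and the regulator of polyamines OAZ1 (-3.52). The matrix protein AGRN (-3.48) and the kinase PTK6 (-3.40) were lower too. HLA-C was at least 10.3-fold lower and SCAMP3 at least 11.0-fold lower, because CSC RNA was above background on 0 of 12 arrays. PLXNA4, a receptor for axon guidance cues, was highest of these genes relative to parental cells, at 1.88 (SE 0.13, adjusted p = 0.0144). The hematopoietic factor LMO2 (1.20), the ribosomal S6 kinase RPS6KA2 (1.15), the lipid enzyme ACSL6 (1.11), the adhesion molecule NCAM1 (1.02) and LTBP1, which stores TGF-beta (0.98), were also higher. VIM was higher by 0.93 and ENG, a marker used for renal stem cells, by 0.41, the latter above background on 6 of 12 arrays in each line. CCND1, CD44, ALDH1A1, MYC, VEGFA, DDIT4 and PAX8 were not called. RPTOR was at least 1.84-fold lower in CSC cells.

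By camera 12 of 27 lists were lower in untreated CSC cells, but 0 after adjustment with an estimated correlation, whose p-values are given unadjusted, and 0 with fry. Sterol genes were called higher in 0 and lower in 10 of 21, 11 when adjusted over the list alone (camera adjusted p = 0.000102; p = 0.192 with an estimated correlation), with the regulator SREBF2 at -0.58. ATF4 targets gave 1 and 10 of 26, 1 and 13 when adjusted over the list alone (camera adjusted p = 0.000596; p = 0.413 with an estimated correlation), with the factor CEBPB lower as well. DNA replication gave 1 and 10 of 26 (camera adjusted p = 0.000596; p = 0.302 with an estimated correlation) and mitosis 0 and 8 of 24 (camera adjusted p = 0.000758; p = 0.312 with an estimated correlation). These were 1 and 13 and 0 and 11 when adjusted over the list alone. Glycolysis gave 0 and 6 of 18, the same when adjusted over the list alone (camera adjusted p = 0.000786; p = 0.324 with an estimated correlation). Oxidative phosphorylation gave 0 and 5 of 27, 4 when adjusted over the list alone (camera adjusted p = 0.000476; p = 0.373 with an estimated correlation), though its median was 0.07 with processed signals. Fatty acid, autophagy, NF-kB and interferon genes and ribosome biogenesis were lower at camera adjusted p from 0.000596 to 0.00785. So were NRF2 targets (camera adjusted p = 0.00266), whose median was 0.10 with processed signals, and each of these calls was lost with an estimated correlation.

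In total, 6216 of 20638 genes differed between untreated cells by limma, 4173 higher and 2043 lower in CSC cells, and 370 of them by at least 1 on the log2 scale, 15 higher and 355 lower. Processed signals, which moved the median of all genes to 0.14, gave 30 genes, 5 higher and 25 lower. Quantile normalization of the channel alone gave 215, and the arrays as units gave 8872, 4190 higher and 4682 lower. With the slide as a block the count fell from 6216 to 2 genes. No test was possible inside a single slide, which held 1 replicate of each line. Without CSC replicate 1, 2 or 3 limma called 0 genes, and without parental replicate 1, 2 or 3 it called 1, 14632 (5926 higher and 8706 lower) and 7. Without parental replicates 1 and 3 together, an alternative chosen after the results were seen, 1 parental replicate remained, so no count is given.

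The comparison of treated cells asks how the lines differ under the drug. Treated CSC cells had far less RNA of HLA-E, the metal-binding protein MT2A and the glycolytic enzyme TPI1 than treated parental cells. They had more RNA of TRPV5 and DCN, which in parental cells were low in replicates 1 and 3 and nearer the CSC level in replicate 2, while the lists of renal and matrix genes did not pass camera.

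Among the called genes with a symbol, HLA-E was lowest relative to parental cells, at -9.73 (SE 0.74, limma adjusted p = 0.00311). TSR1 (-9.72), PTK6 (-9.46), the DNA repair gene TONSL (-9.36, with 1 of 2 other probes opposite), AS3MT (-9.27), MT2A (-9.25) and RPS26 (-8.62) were lower as well. TUBA1B, a tubulin, was at least 461-fold lower, since CSC RNA was above background on 0 of 12 arrays. TRPV5 was highest of these genes relative to parental cells, at 5.19 (SE 1.84, adjusted p = 0.0484), with parental log2 intensities of 6.05, 12.50 and 5.97 in replicates 1, 2 and 3 against a CSC mean of 13.36. The brush border myosin MYO1A (4.74), the collagen receptor DDR2 (4.63) and the proteoglycan DCN (4.19) were also higher. CD44 (-3.55, its 1 other probe opposite), EIF4EBP1 (-3.06), VIM (-2.76), PAX8 (-2.60) and DDIT4 (-2.46) were lower. MTOR and RPTOR were at least 1.92-fold and 9.83-fold lower in CSC cells.

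By camera 15 of 27 lists were lower in treated CSC cells, but 0 after adjustment with an estimated correlation, whose p-values are given unadjusted. Sterol genes were called higher in 0 and lower in 17 of 21, the same when adjusted over the list alone (camera adjusted p = 6.17e-08; p = 0.00634 with an estimated correlation). Glycolysis gave 0 and 13 of 18, 14 when adjusted over the list alone (camera adjusted p = 1.7e-05; p = 0.201 with an estimated correlation), with TPI1 at -5.62. DNA replication gave 1 and 19 of 26, the same when adjusted over the list alone (camera adjusted p = 5.53e-06; p = 0.0574 with an estimated correlation). Oxidative phosphorylation gave 2 and 18 of 27, 7 and 18 when adjusted over the list alone (camera adjusted p = 4.53e-05; p = 0.104 with an estimated correlation). ATF4, NF-kB, NRF2 and HIF targets, mitosis, autophagy, ribosome biogenesis, fatty acid and interferon genes were lower at camera adjusted p from 0.000179 to 0.0296, a call lost for each with an estimated correlation. Ribosomal proteins gave 3 and 11 of 35, 1 and 11 when adjusted over the list alone (camera adjusted p = 0.000766; p = 0.333 with an estimated correlation), with RPS6 at -8.03, and their median of -0.31 flipped with processed signals and, at 0.38, with quantile normalization. Endoplasmic reticulum chaperones (camera adjusted p = 0.0308) flipped from -0.71 to 0.75 with processed signals.

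In total, 14473 of 20638 genes differed between treated cells by limma, 8594 higher and 5879 lower in CSC cells, and 8572 of them by at least 1 on the log2 scale. The median of all genes was 0.57 in the main fit, 1.94 with processed signals and 0.74 with quantile normalization. The split turned round with the slide as a block, at 61 higher and 2695 lower of 2756. It also did with probes above background in all 4 conditions, at 2 and 281 of 283. Without CSC replicate 1, 2 or 3 it was 39 and 1991 of 2030, 18 and 1965 of 1983, and 21 and 1978 of 1999. Without parental replicate 1 or 3 it was 40 and 2370 of 2410, and 46 and 2423 of 2469. The split stayed mostly higher without parental replicate 2, at 12516 and 7156 of 19672. It did so too with processed signals (12400 and 5625), quantile normalization (11234 and 5771) and the arrays as units (9564 and 5618).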

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

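The tests of exchanged labels, of a mixture, of RNA that is not human, of a lower yield, of a response of human cells and of a dye effect, the fit without parental replicates 1 and 3 together and the list of genes that every human cell uses, were chosen after the results were seen; those of other cell types, of poor probe match and of other splits were written before.

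The everolimus response differed between the lines in 5207 genes by limma's test of the difference itself, and in 13 gene lists by camera on the same difference, though in 0 when camera estimated the correlation. These 13 lists were those called higher in the parental response. For the 4 sign patterns of 3 replicates, the real one called 16024 genes in the parental line and 4083 in the CSC replicates alone, and the highest other called 0, so 1 of 4 was as large. For the 10 splits of 6 samples, the real one called 5207 genes for the difference, 6216 between untreated cells and 14473 between treated cells, and the highest other called 0, so 1 of 10 was as large. These splits are too few for a share under 0.05.

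The treated parental RNA of replicates 1 and 3 stood apart from all other RNAs. Without both of them 1 parental replicate remained, whose spread cannot be estimated, so no count of genes is given. An exchange of labels or lines stays open: the highest correlation of these RNAs with an RNA of another condition was 0.605, but that is the pattern itself and would be the same after an exchange of the treated and untreated labels. An exchange of treated parental replicate 2 was not tested. Its highest correlations were 0.926 and 0.933, with the untreated RNA of parental replicates 1 and 3. RNA of several other cell types is argued against only as a joint rise of their markers over untreated RNA, for the 6 of 16 marker lists with enough measured members. Of these, 0 had a median log2 ratio above 1 in both replicates, the medians in replicate 1 running from -1.57 (breast luminal) to -0.22 (renal tubule). KRT19 was their highest single member at 3.71, while POU5F1, the 1 measured member of an untested list, was at 4.15. A ratio to untreated RNA does not show that a marker was absent from treated RNA. For replicate 2, a mixture of untreated-like RNA with 31.2% RNA like that of replicates 1 and 3 is a candidate explanation chosen on these data: a straight line left 2.77 times the residual sum of squares of the mixture curve, but that curve lay below the quartiles of replicate 2 for genes in the bins from -6.40 to -1.48 and at 0.46 and 1.44. A drug response that differed between the cultures, or RNA of a source outside the 6 lists, stays open and was not tested.

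Of 140 genes that every human cell uses, 98.6% were well above background in treated parental RNA, 86.4% in untreated parental RNA and 82.1% and 82.9% in untreated and treated CSC RNA, so fewer were detected outside the treated parental samples. A lower RNA yield or weaker labelling is argued against as the whole cause against parental replicates 1 and 3. Treated CSC RNA and treated parental RNA of these replicates had a highest Spearman correlation of -0.0436 across genes, while a lower yield would keep their order. Treated parental replicate 2 also had 98.6% of these genes above background. Its Spearman correlations with treated CSC RNA were 0.655 to 0.665, so a lower yield stays open there. RNA that is not human stays open at a lowest share of 82.1%, and a response of human parental cells stays open at 86.4%: that pooled share lies above the bound of 85% written for it, but the replicates ran from 84.3% to 92.1%, and the demand that each lie on the same side was added after the pooled share was seen. Poor match to the probes could lower the correlation between pairs of probes for a gene, and the largest drop was 0.170. It stays open because 3 sets of probe pairs were tried and disagreed: the drop ran from 0.102 to 0.170 with all probes, from 0.114 to 0.155 with kept probes and from -0.146 to -0.0810 with the 2 brightest kept probes.

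The CSC response was seen with Cy5 on treated RNA in each array, so a dye effect specific to each gene could add to it and cannot be told apart from the drug. Over 1536 genes with a treated-over-untreated log2 ratio under -3 in both parental replicates 1 and 3, the ratio of parental replicate 2 followed the mean CSC ratio. The slope was 0.554 (SE 0.0195, r = 0.586). A shared dye effect would give such a slope, and so would a response to everolimus that untreated-like cells of parental replicate 2 share with CSC cells. A drug response of the CSC line thus stays open beside the dye effect.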

How the results depend on the processing

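Leaving out parental replicates 1 and 3 together, and the alternatives to the processing of the CSC replicates alone, were chosen after the results were seen. Where no reason is given, the cause was not tested.

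A change of at least 1 on the log2 scale left 8434 genes in the parental response, 189 in the CSC replicates alone, 3133 in the difference, 370 in the untreated and 8572 in the treated comparison. The difference grew to 13917 genes with processed signals, 13910 with the deposited ratios, 7857 with an intensity trend and 12088 with the arrays as units. The untreated comparison shrank to 30 with processed signals and 215 with quantile normalization. The shared CSC fit gave 1 gene with processed signals, 1 with the deposited ratios, 698 with median centring, 393 with scale normalization, 39 with an intensity trend, 312 with the arrays as units, 2960 unpaired and 4083 alone. The CSC replicates alone gave 10847 with median centring, 2447 with the deposited ratios and 6687 with the arrays as units. The parental response gave 2854 alone and 1684 unpaired. With probes above background in all 4 conditions 10988 genes were tested, and calls were 7917 parental, 497 difference, 1194 untreated and 283 treated, the last with 7794 at an unadjusted p under 0.05.

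The correlation of the responses was 0.0524, and -0.0328 with processed signals and -0.306 with median centring. Genes called in both lines were 0 in the shared fit, 1 with processed signals, 1 with the deposited ratios, 323 with median centring, 248 with scale normalization, 29 with a trend, 234 with the arrays as units, 228 with each line alone and 94 unpaired.

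The same replicate number did not pair the lines: after removing line means, r across genes was 0.049, 0.0041 and 0.059 for ratios, -0.056, 0.010 and -0.0025 for untreated and -0.028, -0.018 and 0.028 for treated RNA, though each ratio correlated best with its own number. With the number, which is also the slide, as a block, 2668 genes differed in response, 2 between untreated and 2756 between treated cells.

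Leaving out 1 replicate gave 4659 to 19075 genes in the parental response, 0 to 5833 in the CSC replicates alone, 0 to 0 in the shared CSC fit, 2747 to 18633 in the difference, 0 to 14632 in the untreated and 1983 to 19672 in the treated comparison. Without parental replicates 1 and 3 together, the remaining parental sample had to be assumed to vary like the CSC samples. No counts are given for that fit.

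camera with an estimated correlation called 0 lists in the parental response, 0 in either CSC fit, 0 in the difference and 0 in the untreated and treated comparisons. fry, which tests whether a list moves one way, called 24, 0, 0, 22, 0 and 24 lists for the parental, shared CSC, CSC alone, difference, untreated and treated fits.

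Of the values of named genes across alternatives, 471 kept direction and side of the threshold, 102 only direction and 4 reversed in the parental response. The counts were 379, 46 and 2 in the CSC replicates alone, and 429 and 122, 213 and 207, and 368 and 136, with none reversed, in the difference, untreated and treated comparisons. Those reversed were CCND1 (0.70) and MKI67 (0.68) in parental and FKBP1A (0.16) and CD44 (0.12) in CSC cells with median centring, and MKI67 (0.47) and ALDH1A1 (0.14) in parental cells with the mean of probes.

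Signal over background limited the rest: of 58201 probes, 14426 were kept in untreated and 21396 in treated parental RNA, and 13605 and 16625 in CSC RNA, and ratios against RNA that was well above background on 0 of 12 arrays are lower bounds.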

Other observations

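The test of a small share of treated-like RNA in untreated parental samples was chosen after the result was seen.

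In untreated parental RNA, the excess of replicates 1 and 3 over replicate 2 went weakly with the treated-over-untreated ratio, at a Spearman correlation of 0.228 across genes. A small share of the treated kind of RNA or signal in those untreated samples could give this. Cy3 is also the denominator of the ratio, which would lower this correlation and not raise it. Untreated parental replicates 1 and 3 had Spearman correlations of 0.273 to 0.304 with treated parental replicates 1 and 3. Untreated parental replicate 2 had 0.0179 and 0.0136, which also goes with such a share. The value of 0.228 lay between the bounds written for the test, so it leaves the share open.

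Further lists in the CSC replicates alone passed no camera test. Of 16 endoplasmic reticulum chaperones 1 rose and 5 fell, 1 and 7 when adjusted over the list alone (camera adjusted p = 0.218). HERPUD1 was at 0.87 and the chaperones SDF2L1 and MANF at -1.03 and -0.72, and the list's median of -0.06 became 0.20 with median centring. Of 27 oxidative phosphorylation genes 7 rose and 3 fell, 8 and 4 when adjusted over the list alone, with SDHA at 0.39 and ATP5F1B at -0.47. Their median of -0.03 became 0.16 with median centring (camera adjusted p = 0.894). Of 26 DNA replication genes 2 rose and 5 fell, the same when adjusted over the list alone (camera adjusted p = 0.294), with the helicase subunits MCM5 at -0.97 and MCM2 at 0.80. Of 13 fatty acid genes 0 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.698): FASN, the fatty acid synthase, at -0.92 and FADS2 at -0.43. Their median of 0.01 differed in sign from the mean of -0.09 and became -0.17 with processed signals, -0.09 with the deposited ratios and -0.03 with median centring. Of 24 ribosome biogenesis genes 4 rose and 3 fell, 4 and 4 when adjusted over the list alone (camera adjusted p = 0.46), with NIP7 at 0.73 and NPM1 at -0.48.

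Of 13 receptor feedback and FOXO genes 3 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.698), with FOXO3 at 1.03 and BCL6 at 1.17. Their median of -0.01 differed in sign from the mean of 0.20 and became 0.13 with median centring. Of 15 p53 targets 3 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.894), with PLK3 at -0.65. Of 14 immediate early genes 2 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.894), with the phosphatase DUSP1 at 0.92. Of 17 mesenchymal genes 1 rose and 3 fell, 2 and 3 when adjusted over the list alone (camera adjusted p = 0.15), with ZEB2 at 0.56 and a median that flipped to 0.09 with median centring. Of 16 matrix genes 4 rose and 1 fell, 5 and 2 when adjusted over the list alone (camera adjusted p = 0.643), with COL8A1 at 0.76 and the protease inhibitor TIMP1 at -0.76. The other 9 lists, of epithelial, sterol, renal tubule, fibroblast, interferon, leukocyte, NF-kB, NRF2 and endothelial genes, had camera adjusted p from 0.383 to 1.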
